A study of Mus musculus with 6 samples.

How the data were processed

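The series comprised 6 samples of mouse bone marrow-derived macrophages, cells grown out of marrow into macrophages. All were treated with lipopolysaccharide (LPS, a bacterial cell wall component sensed through TLR4) for 24 h. Total RNA was made into strand-specific libraries, per the labels' protocols. Groups and replicate numbers came from the sample titles, with 3 libraries from Capns1 knockout (KO) cells and 3 from wild-type (WT) cells. The genotype field names a different Capns number in each KO sample, whereas the design text names Capns1 for the whole group, so Capns1 was examined in each library first. The labels do not say whether replicates were separate animals or cultures. The p-values therefore measure only the spread between these samples, which may be technical.

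The authors deposited a table of read counts per gene and a table of FPKM values for 16266 genes. The submitters' processing notes name fastp, HISAT2, HTSeq and the mm10 genome build. Versions and the strand setting of counting are not given in the sources used here. In the deposited tables, FPKM equalled the count divided by a single length per gene and by the column total. This held within 1% for 99.99% of values of at least 10 counts. Total counts ranged from 32631163 to 40913819 per library. At this depth 3 counts, the limit that a count of 0 allows, correspond to 0.0733 to 0.0919 CPM, which is the count divided by the library total and brought to a common scale. Such limits cover counting error only. Gene positions and biotypes came from RefSeq on GRCm38.p6, the assembly of mm10, through the Entrez identifiers of the table, which matched for 16189 genes. Mitochondrially encoded genes and ribosomal RNA were not analysed here.

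Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, quasi-likelihood F test of group). Benjamini-Hochberg adjustment was over 12219 genes, and a gene with an adjusted p under 0.05 is termed called. CPM values use the whole column total. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. Log2 fold changes are KO minus WT. Gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry. Fry tests whether the genes of a list move on balance in one direction, without comparing them with other genes. Adjustment was over the 28 gene lists with at least 2 tested members and separately over 14 cell type marker lists. Of 859 list entries, 22 were matched through another symbol and 33 were not analysed here. Annotation terms of 10 to 500 tested genes were tested with one-sided Fisher's exact tests against tested genes with a term, with genes called higher and lower apart. The design, the lists and the alternatives not named as later additions were set before the data were examined.

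Named genes were chosen by a rule. It took the calpain system, and the 10 largest rises and 10 largest falls among called protein-coding genes whose groups did not overlap and whose mean CPM was at least 5, leaving out Gm-numbered and Rik symbols. It also took the 10 called genes of smallest adjusted p, up to 4 called members per list (or 2 of smallest p where none was called), and Nlrp3, Il1b, Casp1, Gsdmd, Il18, Tnf, Il6, Nos2, Il10 and Arg1. Genes sharing sequence with near-identical copies were identified by the share of their 32-base words found in transcripts of other genes. Values of a few genes that the rule takes are not reported here.

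The procedure was tested on simulated counts with the means, library sizes and dispersions of these 12219 genes and 200 changed genes. For the KO and WT comparison, edgeR recovered 0% of changes of 1.2-fold, 38% of 1.5-fold, 78% of 2-fold and 92% of 4-fold. Of its calls, 7.96% were unchanged genes. For DESeq2 1.42.0, an alternative, 13.0% of calls were unchanged genes. Simulated genes varied independently and few of them changed, so these shares may differ in the data. In simulated lists, camera and fry each called the 1 shifted list. Of 20 unshifted lists, camera called 0 and fry 1. Alternatives comprised other scalings, limma-voom, DESeq2, other low-count filters, protein-coding genes only and a fold threshold. Further ones were limma-trend on log2 FPKM with pseudocounts of 1 and 0.1, the former also with FPKM of at least 1 in 3 samples, a replicate block and leaving out each library. Removing a gene length or GC trend, leaving out genes that share over 30% of these words or have no value for them, and leaving out both libraries that stand apart were added after the data were seen.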

Results

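RNA from LPS-treated bone marrow-derived macrophages was sequenced in 3 Capns1 KO and 3 WT libraries, all collected after 24 h of LPS, with 32631163 to 40913819 counts each. The study's title concerns loss of Capns1 in myeloid cells, inflammasome activation and mitochondrial function. The comparison asks which transcripts differ between KO and WT macrophages under LPS. No libraries without LPS were analysed here, so the response to LPS itself was not measured.

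Capns1, the small regulatory subunit shared by calpains 1 and 2, lies on chromosome 7 at 30186934 to 30198883 (GRCm38). It had 497 ± 22.3 CPM in WT and 9.53 ± 0.405 in KO libraries (SD, n = 3 each). Counts ranged from 298 to 370 in the KO libraries and from 17055 to 21331 in the WT libraries. Each of the 3 KO libraries thus carried the loss, including those whose genotype field names another number. The log2 fold change was -5.73 ± 0.12 SE in edgeR (adjusted p = 1.77e-10). A two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. The catalytic subunits Capn1 (-0.12, adjusted p = 0.497) and Capn2 (0.032, adjusted p = 0.876) and the inhibitor calpastatin, Cast (0.17, adjusted p = 0.309), were not called. Of the 9 tested members of the calpain list, Capns1 alone was called (camera adjusted p = 7.94e-06, and adjusted p = 0.524 with an estimated correlation). The list did not pass with limma-voom, the 3 limma-trend settings, or a length or GC trend removed (adjusted p = 0.0710 to 0.212). Cox7a1, a cytochrome oxidase subunit gene on the opposite strand at 30184171 to 30186030, was singled out after its values were seen, with a log2 fold change of -4.44 (adjusted p = 1.12e-04; 0.0939 ± 0.0708 CPM in KO and 2.10 ± 0.0956 in WT, SD, n = 3). It lies close to Capns1 and the strand setting of counting is not given, so its value is uncertain. On the log2(FPKM + 1) scale, which understates the change of low genes, its log2 fold change was -2.22.

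In edgeR, 1790 of 12219 genes differed, 1031 higher and 759 lower in KO. Of these, 565 and 132 differed by more than 2-fold. KO and WT libraries did not overlap for 33.6% of tested genes, against 10% by chance. The largest rises included the lectin Mgl2, at 11.5 ± 0.489 CPM in KO and 0.15 ± 0.12 in WT (SD, n = 3), a log2 fold change of 6.15 from near the counting floor. The scavenger receptor Marco stood at 1738 ± 331 CPM in KO and 105 ± 19.7 in WT (SD, n = 3), a log2 fold change of 4.04 ± 0.18 SE (adjusted p = 3.01e-07). Cyp4f18 (4.38), Plekhg1 (3.96), Gdpd3 (3.54) and Ltbp2 (2.99) were also among the 10 largest rises. Plekhg1 and Cyp4f18 stood at 0.715 and 0.729 CPM in WT. On the log2(FPKM + 1) scale the log2 fold changes were 2.66 for Mgl2, 2.37 for Cyp4f18, 0.63 for Plekhg1 and 1.31 for Ltbp2. After Capns1, the largest falls included Arg2 (log2 fold change -2.26 ± 0.16 SE, adjusted p = 6.14e-06), the mitochondrial arginase. Further large falls were Svip (-2.17), Tlcd2 (-2.06), Ctse (-2.03), Adra1a (-2.01), Spon1 (-1.72), Gpr162 (-1.64) and Map4k1 (-1.61), with Svip at -1.29, Adra1a at -1.13 and Spon1 at -0.87 on the log2(FPKM + 1) scale. The 10 genes of smallest adjusted p also held the lectin Clec10a (2.53), Arl2bp (2.80), Rpl26 (2.24), Rps2 (1.92) and Gm42226 (7.20), the last at 0.0901 CPM in WT, near the counting floor, and at a log2 fold change of 2.21 on the log2(FPKM + 1) scale. H2-Q7 (3.78), H2-Q6 (-2.08), Ly6a (2.93), Ly6c2 (2.83) and Rpl21 (3.56) ranked among the largest as well, but they share 16.8 to 48.9% of their sequence words with other genes. Mgl2, Clec10a, Rpl26, Rps2 and Tlcd2 share 14.1 to 48.5%, so the values of all 10 are uncertain. Without WT replicate 1, KO replicate 1 or KO replicate 3, the calls numbered 1138, 1119 and 1149. Calls lower in KO numbered 434, 359 and 402 in turn, and 431 without WT replicate 2.

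Among inflammasome genes, 2 of 24 tested genes rose and 5 fell (2 and 5 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.136). The cytokine Il1a (log2 fold change 1.10 ± 0.20 SE, adjusted p = 0.00401) and the adaptor Pycard (log2 fold change 0.60 ± 0.11 SE, adjusted p = 0.00433) rose. The thioredoxin inhibitor Txnip (-0.57, adjusted p = 0.00500) and the ATP-gated channel P2rx7 (-0.47, adjusted p = 0.00904) fell. The sensor Nlrp3 had 74.3 ± 1.93 CPM in KO and 90.5 ± 3.57 in WT (SD, n = 3), a log2 fold change of -0.31 ± 0.094 SE (adjusted p = 0.0498). This call lay at the threshold and was lost under 18 of 24 alternatives, including each of the 6 that left out 1 library. Il1b (log2 fold change -0.032 ± 0.13 SE, adjusted p = 0.911), Casp1 (-0.00254, adjusted p = 0.992), Gsdmd (-0.17, adjusted p = 0.307) and Il18 (-0.36, adjusted p = 0.269) were not called. Without WT replicate 3 and KO replicate 2, which stood apart from the other libraries of their groups, the list passed as lower in KO (adjusted p = 0.0109) and the log2 fold change of Il1a was 0.70. Gsdmd and Il18 were then called as lower (adjusted p = 0.0180 and 4.13e-04), and Il18 was also called without KO replicate 2 alone. With both left out, the remaining libraries also differ by group on the second principal component (8.21 and 12.4 in WT, -12.6 and -10.4 in KO). An effect of genotype and that difference cannot be told apart in this subset.

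**Figure D1:**
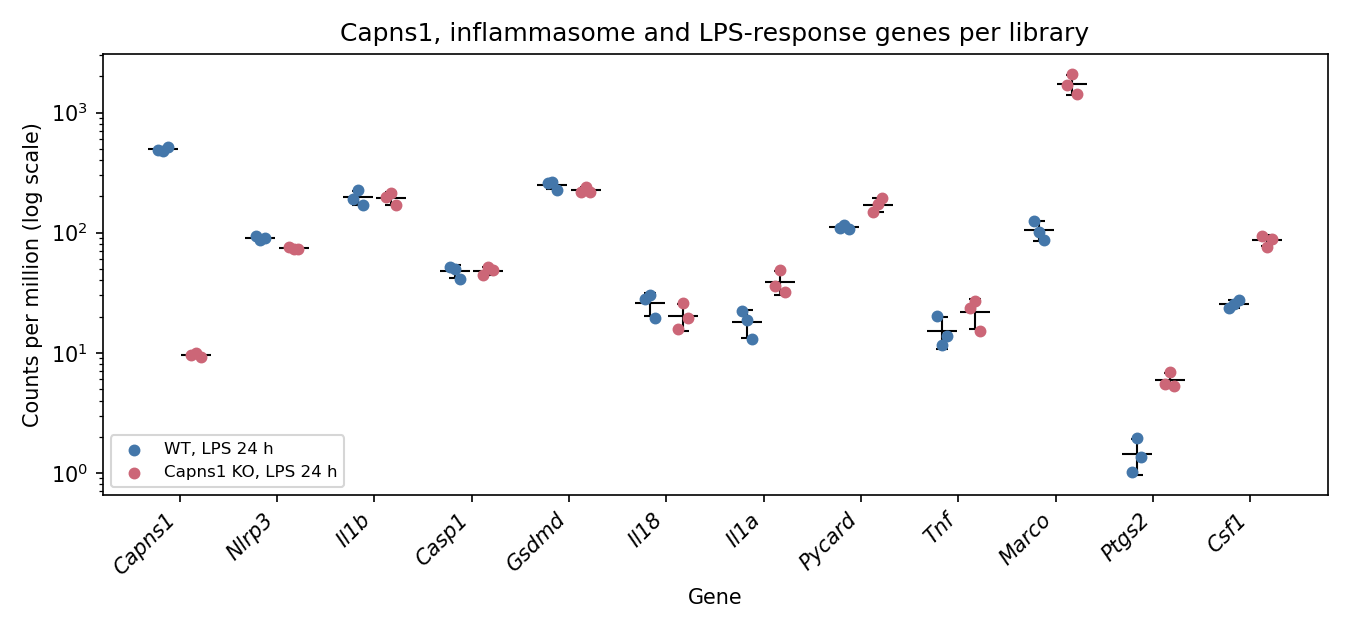
CPM per library (log axis) of Capns1, inflammasome and LPS-response genes, where points are libraries (n = 3 per group), horizontal marks are means and bars are SD. Capns1 averaged 9.53 CPM in KO and 497 in WT, and Il1b 194 and 196.

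LPS-induced cytokines and mediators moved in both directions. In this list, 8 of 26 tested genes rose and 3 fell (8 and 4 adjusted over the list alone), with camera adjusted p = 5.24e-04, and adjusted p = 0.524 with an estimated correlation. The list did not pass with limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1), or with a length trend removed (adjusted p = 0.0895, 0.0875 and 0.152). Beside Marco, the macrophage growth factor Csf1 (log2 fold change 1.73 ± 0.11 SE, adjusted p = 3.39e-06), the prostaglandin E synthase Ptges (1.02) and Tnfsf9 (2.04) rose. Tnf (0.51, adjusted p = 0.185), Nos2 (-0.51, adjusted p = 0.185), Il10 (-0.31, adjusted p = 0.503) and Arg1 (0.84, adjusted p = 0.202) were not called, and Il6 was below the count filter. Arg1 was called with limma-trend on log2(FPKM + 1), and Il10 without both libraries that stood apart (adjusted p = 0.0441 and 0.00433). For Il10 this is the subset whose groups also differ on the second principal component. Among chemokines, 7 of 19 tested genes rose and 2 fell (7 and 3 adjusted over the list alone). Rises included Cxcl14 (1.34), Cx3cl1 (2.05), Cxcl1 (1.58) and Cxcl5 (1.82). In the same libraries, markers of fibroblasts and marrow stroma were higher in KO (median log2 fold change 0.91, camera adjusted p = 2.90e-08, and adjusted p = 0.0457 with an estimated correlation). The chemokine list did not pass in edgeR with the 6 libraries (camera adjusted p = 0.0840, and adjusted p = 0.70 with an estimated correlation), nor by fry (adjusted p = 0.187). The list's median of -0.043 and mean of 0.31 differed in sign. It passed as higher in KO with no low-count filter, with a replicate block in edgeR or DESeq2, and without WT replicate 2 or KO replicate 1 (adjusted p = 0.0138 to 0.0499). Of alternative activation genes, 2 of 20 tested genes rose and 2 fell (2 and 2 adjusted over the list alone), with camera adjusted p = 0.00755, and adjusted p = 0.524 with an estimated correlation. Clec10a and Mgl2 rose, and the chemokine Ccl24 (-2.55) and the lipid receptor Trem2 (-0.51) fell. That list did not pass with limma-voom, the 3 limma-trend settings, or a length or GC trend removed (adjusted p = 0.165 to 0.306), and had adjusted p = 0.0568 without WT replicate 1. In the immediate early and heat shock list, 5 of 21 tested genes rose and 1 fell (8 and 2 adjusted over the list alone), with camera adjusted p = 0.0101, and adjusted p = 0.524 with an estimated correlation. The transcription factors Fosl1 (2.09), Myc (1.21) and Egr1 (0.96) rose. The list did not pass with limma-trend on genes with FPKM of at least 1 in 3 samples, or with a length or GC trend removed (adjusted p = 0.0545 to 0.0757). The call of Trem2 was lost without WT replicate 2, KO replicate 1 or KO replicate 3 (adjusted p of up to 0.0958), and that of Egr1 without KO replicate 1 or KO replicate 3 (up to 0.0526). On the log2(FPKM + 1) scale the log2 fold changes were 1.11 for Tnfsf9, 1.06 for Cx3cl1, 0.88 for Cxcl5 and -0.91 for Ccl24.

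Several interferon response genes fell in KO. For type I interferon genes, 1 of 34 tested genes rose and 6 fell (1 and 7 adjusted over the list alone), with camera adjusted p = 4.07e-04, and adjusted p = 0.70 with an estimated correlation. By fry this list did not pass (fry adjusted p = 0.182). The antiviral gene Rsad2 fell from 57.2 ± 3.94 CPM in WT to 28.6 ± 1.68 in KO (SD, n = 3; log2 fold change -1.02 ± 0.11 SE, adjusted p = 9.72e-05). Ifit2 (-0.97), Cmpk2 (-0.66) and Ifi44 (-0.71) fell too. Among interferon-gamma type and class I genes, 1 of 24 tested genes rose and 10 fell (1 and 10 adjusted over the list alone), with camera adjusted p = 0.00394, and adjusted p = 0.524 with an estimated correlation. The guanylate-binding protein Gbp5 (-0.85), the checkpoint ligand Cd274 (-0.46) and the class I activator Nlrc5 (-0.49) fell. H2-K1 (0.49) was higher, but shares 21.5% of its sequence words with other genes. For MHC class II genes, 4 of 11 tested genes rose and 1 fell (4 and 3 adjusted over the list alone), with camera adjusted p = 0.221. Rises were H2-DMb1 (2.63), which shares 30.8% of its words with other genes, H2-Ab1 (0.75), H2-Aa (0.68) and H2-Eb1 (0.70). In TLR4 signalling, 1 of 24 tested genes rose and 5 fell (1 and 7 adjusted over the list alone), with camera adjusted p = 0.0754, and adjusted p = 0.538 with an estimated correlation, but fry adjusted p = 0.0328. The list passed camera, as lower in KO, with DESeq2, limma-voom, no low-count filter, limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1), a replicate block in DESeq2, a GC trend removed, and without WT replicate 2 (adjusted p = 0.0383 to 0.0479). The falls included the kinases Irak4 (-0.48) and Ikbke (-0.44), Traf6 (-0.52) and the LPS co-receptor Cd14 (-0.34). Of NF-kB genes, 1 of 22 tested genes rose and 1 fell (0 and 1 adjusted over the list alone), with camera adjusted p = 0.885. These were the fall of Birc3 (-0.43), which shares 11% of its words with other genes, and the rise of the ribonuclease Zc3h12a (0.46), and the list's median (0.042) was above 0 while camera pointed down. The calls of H2-Eb1, Ikbke, Cd14, Birc3 and Zc3h12a were lost without WT replicates 1 or 2 or KO replicates 1 or 3, and that of Cd14 also without WT replicate 3, with adjusted p of up to 0.111, 0.105, 0.133, 0.0868 and 0.109. Traf6 lost its call without WT replicate 1, KO replicate 1 or KO replicate 3 (up to 0.0928), H2-Aa without WT replicate 1 or KO replicate 3 (up to 0.0881), Nlrc5 without WT replicate 1 (0.0619) and Cd274 without KO replicate 3 (0.0518). The call of Ifi44 was lost with a replicate block in DESeq2.

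Of cholesterol and lipid handling genes, 0 of 25 tested genes rose and 12 fell (2 and 15 adjusted over the list alone), with camera adjusted p = 7.94e-06, and adjusted p = 0.524 with an estimated correlation. The lipid carrier Apoe went from 25958 ± 1464 CPM in WT to 11258 ± 286 in KO (SD, n = 3), a log2 fold change of -1.23 ± 0.087 SE (adjusted p = 5.63e-06). The desaturase Scd2 (-1.16) and the sterol transporter Abcg1 (-0.65) fell. The annotated term cholesterol biosynthetic process held 12 of 23 genes against 1.42 expected, adjusted p = 1.55e-06 for genes lower in KO (one-sided Fisher's exact test). That test takes genes as independent, so its p can be too small where genes move together. In the autophagy and lysosome list, 0 of 31 tested genes rose and 5 fell (0 and 8 adjusted over the list alone), with camera adjusted p = 0.00728, and adjusted p = 0.524 with an estimated correlation. Gpnmb (-0.64), the membrane protein Lamp1 (-0.35) and the cathepsins Ctsb (-0.36) and Ctsl (-0.45) fell. Calls of Lamp1, Ctsb and Ctsl were each lost without KO replicate 1 or KO replicate 3, with adjusted p of up to 0.0964, 0.0942 and 0.113 over the libraries left out. Lamp1 lost its call also without WT replicate 1, Ctsb without WT replicate 2 or 3, and Ctsl without WT replicate 2 (log2 fold change -0.28), and the calls of Ctsb and Ctsl were lost with limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1).

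Nuclear genes of oxidative phosphorylation were shifted slightly upward in KO. The median log2 fold change was 0.22 for complex I, 0.25 for complexes II to IV and 0.24 for ATP synthase. For complex I, 4 of 36 tested genes rose and 0 fell (4 and 0 adjusted over the list alone), with camera adjusted p = 0.00728, and adjusted p = 0.701 with an estimated correlation. For complexes II to IV, 4 of 24 tested genes rose and 0 fell (5 and 0 adjusted over the list alone), with camera adjusted p = 0.0160, and adjusted p = 0.701 with an estimated correlation. For ATP synthase, 2 of 16 tested genes rose and 0 fell (4 and 0 adjusted over the list alone), with camera adjusted p = 0.0221, and adjusted p = 0.70 with an estimated correlation. Called members included Ndufa11 (0.47, adjusted p = 0.0140), Cyc1 (0.40, adjusted p = 0.0180) and Atp5g1 (log2 fold change 0.83 ± 0.10 SE, adjusted p = 3.09e-04). Atp5g1 shares 13.6% and Ndufa11 8.75% of their sequence words with other genes. The call of Ndufa11 was lost without KO replicate 3 (adjusted p = 0.0523) and that of Cyc1 without WT replicate 1 (0.0518) or with a GC trend removed. Ribosomal protein genes had a median of 0.20, and 5 of 40 tested genes rose and 0 fell (5 and 0 adjusted over the list alone), with camera adjusted p = 2.47e-04, and adjusted p = 0.70 with an estimated correlation. By fry neither these genes (adjusted p = 0.159) nor the 3 oxidative phosphorylation lists passed (adjusted p = 0.182, 0.182 and 0.152). Rps2 (1.92), Rps18 (1.31) and Rpl30 (1.19) share 12.6 to 48.5% of sequence words with other genes. On the second principal component, which held 15.9% of variance, KO replicate 2 (25.5) stood apart from the other KO libraries (-12.6 and -10.4). WT replicate 3 (-23.2) stood apart from the other WT libraries (8.21 and 12.4). The complex I list had camera adjusted p = 0.102 without WT replicate 3, 0.13 without KO replicate 2 and 0.617 without both. The other 2 oxidative phosphorylation lists lost their calls likewise (0.113 and 0.113, then 0.14 and 0.136, then 0.617 and 0.513). For ribosomal proteins it was 0.149 without both. With a gene length trend removed, camera adjusted p was 0.179 for complex I, 0.191 for complexes II to IV, 0.179 for ATP synthase and 0.0906 for ribosomal proteins. This setting and the removal of both libraries were added after the data were seen. With both removed, WT (8.21 and 12.4) and KO libraries (-12.6 and -10.4) also differ on the second principal component. The values of that setting therefore cannot be read as an effect of genotype alone.

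Of glycolysis genes, 9 of 24 tested genes rose and 1 fell (10 and 1 adjusted over the list alone), with camera adjusted p = 0.0286, and adjusted p = 0.569 with an estimated correlation. Rises included Eno1 (log2 fold change 0.53 ± 0.091 SE, adjusted p = 0.00253), which shares 28.4% of its sequence words with other genes. The lactate exporter Slc16a3 (0.76), Pfkl (0.45) and Ldha (0.43) rose too, and Ldha shares 18.9%. The glycolysis list had adjusted p = 0.15 without WT replicate 1 and 0.0567 with genes left out that share over 30% of their words or have no value for them, and the call of Ldha was lost without WT replicate 1 (adjusted p = 0.0737). Of genes for mitochondrial dynamics and quality control, 1 of 33 tested genes rose and 1 fell (0 and 0 adjusted over the list alone), with camera adjusted p = 0.498. Phb2 (0.31) rose. Of mitochondrial biogenesis genes, 1 of 16 tested genes rose and 0 fell (0 and 0 adjusted over the list alone), with camera adjusted p = 0.946, the rise being Pprc1 (0.64). The call of Phb2 was lost without each of the 6 libraries in turn (adjusted p of up to 0.162), with no low-count filter and with a length trend removed. That of Pprc1 was lost without WT replicate 1, WT replicate 2, KO replicate 1 or KO replicate 3 (up to 0.119) and with the 3 limma-trend settings. The biogenesis list had a median of -0.044 and a mean of 0.020, opposite in sign. In the TCA cycle list, 0 of 19 tested genes rose and 0 fell (0 and 0 adjusted over the list alone), with camera adjusted p = 0.346, and Idh3a (0.44, adjusted p = 0.0504) and Mdh2 (0.32, adjusted p = 0.0549) had the smallest p. These 2 genes were called as higher under 13 and 14 of 24 alternatives, and the list passed with a GC trend removed (adjusted p = 0.0369).

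**Figure D2:**
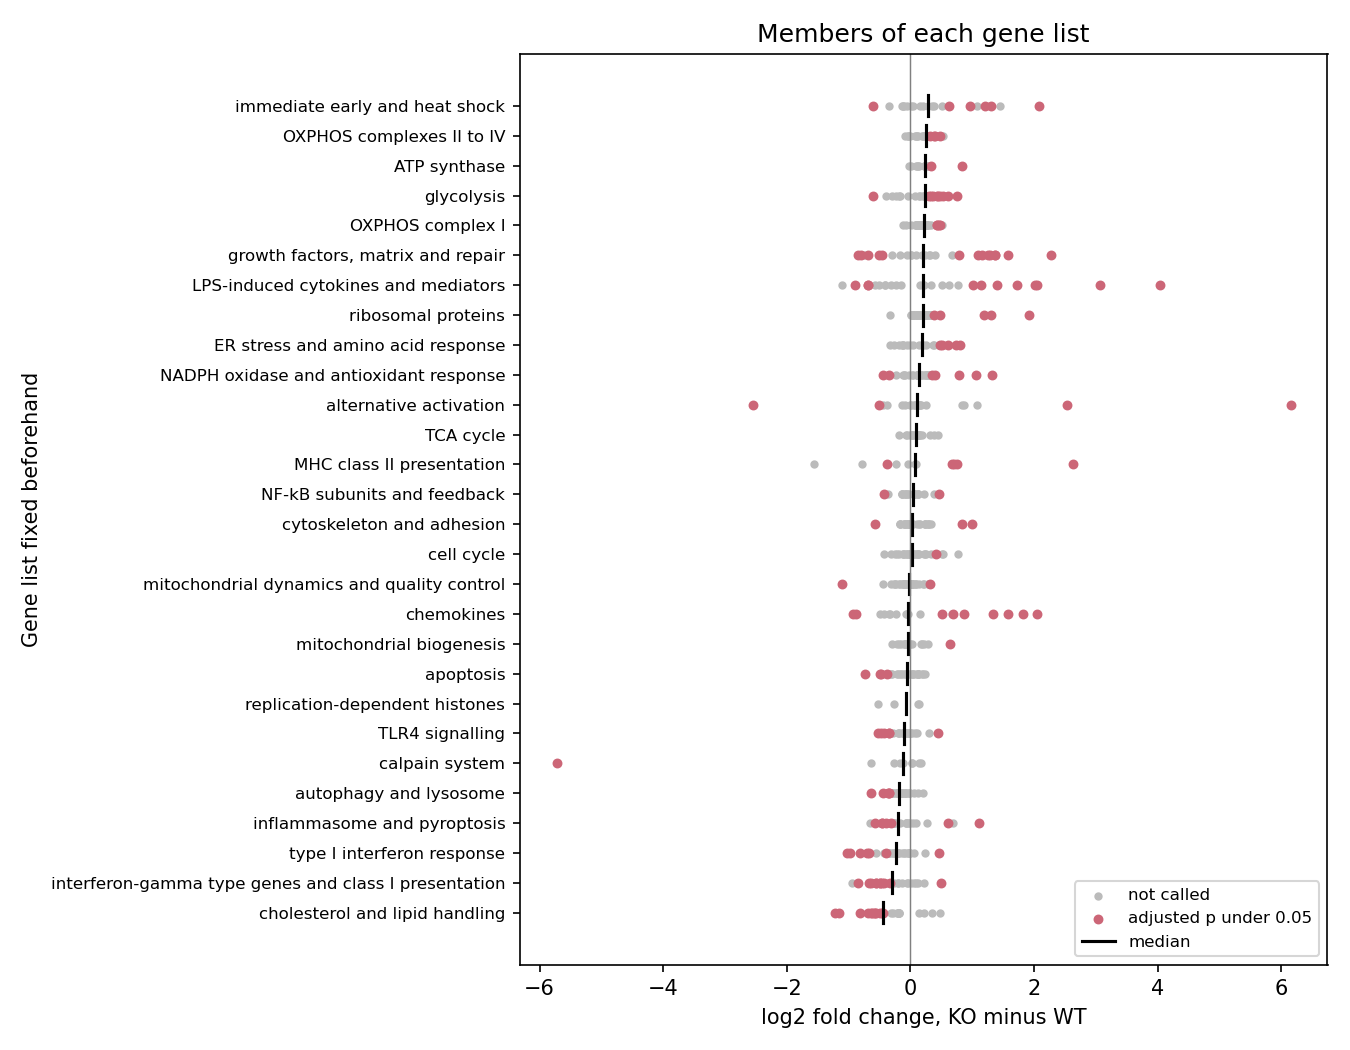
Log2 fold change (KO minus WT, horizontal axis) of each tested member of the gene lists, where red points passed adjusted p under 0.05 in edgeR, grey points did not and black bars are list medians. The cholesterol and lipid list has a median of -0.44.

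Growth factor, matrix and repair genes changed both ways. In this list, 9 of 28 tested genes rose and 5 fell (10 and 7 adjusted over the list alone), with camera adjusted p = 0.0252, and adjusted p = 0.524 with an estimated correlation. The protease inhibitor Timp1 (1.25), the gelatinase Mmp2 (1.37) and osteopontin, Spp1 (1.16), rose, and Spp1 shares 14.1% of its sequence words with other genes. The list did not pass with limma-voom, CPM of at least 1 in 3 samples, the 3 limma-trend settings, a length or GC trend removed, or without WT replicate 1 (adjusted p = 0.0545 to 0.101). Markers of fibroblasts and marrow stroma were also higher in KO. Of these, 6 of 11 tested genes rose and 0 fell (8 and 0 adjusted over the list alone), with camera adjusted p = 2.90e-08, and adjusted p = 0.0457 with an estimated correlation. The proteoglycan Dcn stood at 53.9 ± 4.14 CPM in KO and 15.5 ± 1.93 in WT (SD, n = 3), a log2 fold change of 1.78 ± 0.13 SE (adjusted p = 5.63e-06). Pdgfra (1.91), Col1a2 (1.16) and Sparc (0.86) rose, and Col3a1 (0.27, adjusted p = 0.306), named after its values were seen, was not called. Pdgfra had a log2 fold change of 0.52 on the log2(FPKM + 1) scale. No other of the 14 marker lists tested passed camera in edgeR with the 6 libraries and no trend removed. The eosinophil list, of 4 tested genes, passed as lower in KO with limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1), with a length trend removed, and without WT replicate 3 (adjusted p = 0.0285, 0.0347, 0.0468 and 0.0457). In the monocyte list, 4 of 8 tested genes rose and 2 fell (4 and 2 adjusted over the list alone), with camera adjusted p = 0.515. Plac8 (-1.32) fell, and Fn1 (1.29) and Hp (0.62) rose. In the granulocyte precursor list, 2 of 15 tested genes rose and 6 fell (3 and 6 adjusted over the list alone), with camera adjusted p = 0.122. The granule proteases Prtn3 (-0.93) and Ctsg (-1.08) fell and S100a8 (0.75) rose. That list passed, as lower in KO, without WT replicate 1, WT replicate 3 or KO replicate 3 (adjusted p = 0.0388, 0.0375 and 0.0241), and with a length trend removed (0.0468), where the log2 fold change of S100a8 was 0.49. Of macrophage markers, 2 of 12 tested genes rose and 1 fell (2 and 2 adjusted over the list alone), with camera adjusted p = 0.935. The complement gene C1qb (0.61) rose and Cd14 fell. C1qa (0.30, adjusted p = 0.0415) was called as higher, but lost its call without each of the 6 libraries in turn (adjusted p of up to 0.154) and under 10 of 24 alternatives in all. The call of Cd14 was lost without any 1 library other than KO replicate 2.

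**Figure D3:**
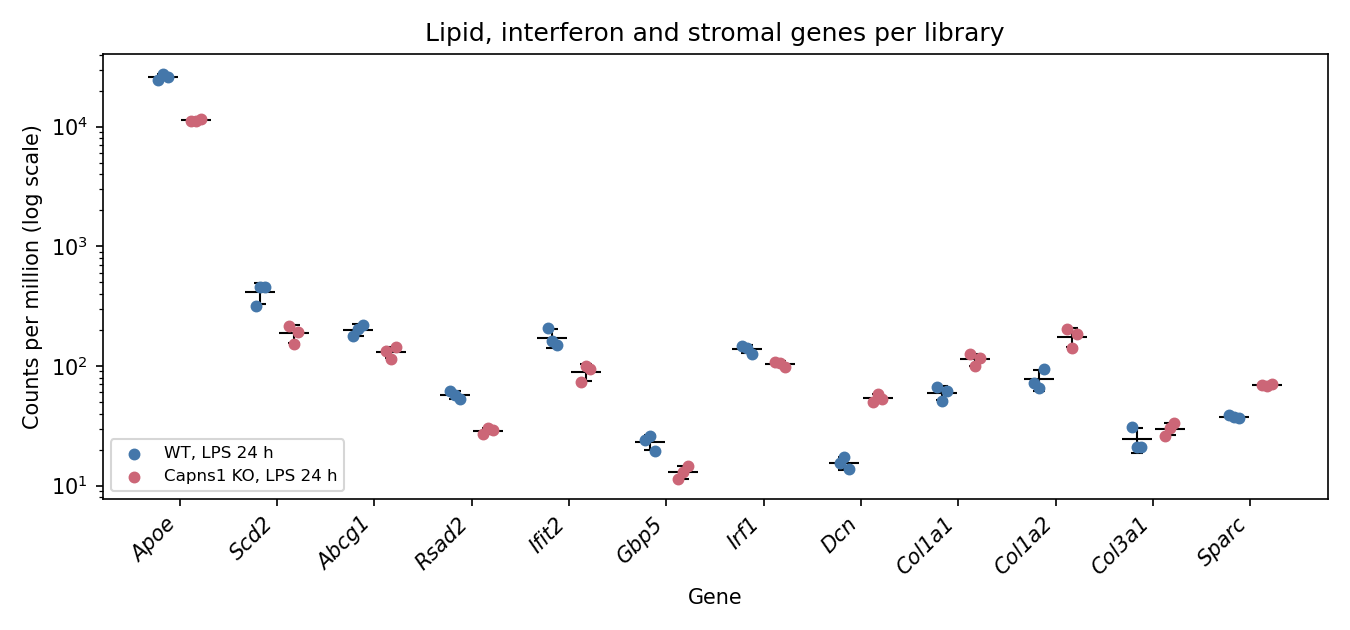
CPM per library (log axis) of lipid, interferon and stromal genes, where points are libraries (n = 3 per group), horizontal marks are means and bars are SD. Dcn averaged 53.9 CPM in KO and 15.5 in WT, and Col3a1 29.9 and 24.4.

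The 10 most abundant genes took 19.6 ± 0.624% of counts in KO and 20.6 ± 0.708% in WT (SD, n = 3). The two-sided exact permutation p was 0.1, the smallest that 3 against 3 allows, or 0.4 adjusted over 4 measures. Exact permutation p was 0.2 for genes detected, 0.3 for library size and 1 for the haemoglobin share. Libraries within a group differed beyond sampling noise, with a chi-square of counts per degree of freedom of 12.8 to 61.6.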

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

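Removing length or GC trends, leaving out genes that share sequence and leaving out both libraries that stand apart were chosen after the data were seen. Capns1 kept its direction and call under all 24 alternatives. The genes called between KO and WT numbered 1790 (1031 genes called higher in KO, 759 genes called lower in KO). Tested against a fold of 1.5, stricter by construction, they numbered 448 (366 and 82). Leaving out 1 library gave 1119 to 1741 (704 to 1039 and 359 to 742), and 11 to 33 of 131 called named genes lost their call (29, 23 and 12 without WT replicates 1, 2 and 3, 27, 11 and 33 without KO replicates 1, 2 and 3). Without both libraries that stand apart there were 3186 (1681 and 1505). These were picked for their distance from the rest, which lowers the spread. The libraries kept also differ by group on the second principal component (8.21 and 12.4 in WT, -12.6 and -10.4 in KO). The higher number of calls is therefore no gain in evidence. Other scalings, filters and tools stayed within 1.5 times. Deviations of same-numbered libraries from their group means correlated at -0.098, 0.23 and 0.18 across genes. Not every library correlated best with its own number. So few values cannot settle whether replicate numbers pair the samples. A replicate block gave 2526 calls (1362 and 1164), and 2281 in DESeq2.

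Of gene lists fixed beforehand, 14 passed, but 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 5 with a length trend removed. By fry 12 passed, 9 of them also by camera. The calpain list is among the 14, the 12 and the 9, and the targeted gene Capns1 was its only called member. Of cell type marker lists 1 passed, but 2 with limma-trend on log2(FPKM + 1), 2 on log2(FPKM + 0.1), 3 with a length trend removed and 1 to 3 without 1 library. The cause was not tested. Annotated pathway terms numbered 186, and 164 with DESeq2 calls. Over named genes and alternatives, 253 values lost and 42 gained a call; for lists these were 57 and 30. No called value changed sign, whereas 23 gene and 30 list values called under neither setting did. Nlrp3 ranged in log2 fold change from -0.44 to -0.23 and in adjusted p from 0.0196 to 1, the latter against a fold of 1.5. Leaving out mitochondrially encoded and ribosomal RNA genes was not run, as these were not analysed here. At this depth and n, edgeR recovered 0% of simulated 1.2-fold changes and DESeq2 8%, so changes of this size can be missed. Far fewer genes were called in the simulation than in the data, which makes its adjusted p stricter. The share missed in the data may therefore differ.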

Other observations

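The term collagen-containing extracellular matrix had the smallest adjusted p of the gene ontology terms among genes higher in KO. It held 63 of 178 genes against 15.3 expected, adjusted p = 3.21e-20, and growth factor activity held 21 of 60 genes against 5.17 expected, adjusted p = 3.14e-06 (one-sided Fisher's exact tests). Such tests of terms take genes as independent, so their p can be far too small where genes move together. No term was tested with an estimated correlation. Markers of fibroblasts and marrow stroma rose with these terms (median log2 fold change 0.91, camera adjusted p = 2.90e-08, and adjusted p = 0.0457 with an estimated correlation). Of 3107 gene ontology terms, 116 passed for higher and 48 for lower genes. Among pathways, steroid biosynthesis held 9 of 17 genes against 1.16 expected, adjusted p = 1.38e-04 for genes lower in KO. In the list for ER stress and amino acid response, 5 of 22 tested genes rose and 0 fell (7 and 2 adjusted over the list alone), with camera adjusted p = 0.0935, and adjusted p = 0.524 with an estimated correlation, but fry adjusted p = 0.0328. It passed camera with the 3 limma-trend settings, a replicate block in DESeq2, a GC trend removed, and without KO replicate 3 (adjusted p = 0.0308 to 0.0435). The chaperones Pdia4 (0.73) and Calr (0.61) and the asparagine synthetase Asns (0.80) rose. In the antioxidant list, 5 of 28 tested genes rose and 2 fell (6 and 3 adjusted over the list alone), with camera adjusted p = 0.146, or adjusted p = 0.0444 with a GC trend removed. Nqo1 (1.32), Hmox1 (0.79) and the cystine transporter Slc7a11 (1.06) rose, and the oxidase subunit Ncf4 (-0.44) fell. Of apoptosis genes, 0 of 29 tested genes rose and 4 fell (0 and 5 adjusted over the list alone), with camera adjusted p = 0.136, and adjusted p = 0.524 with an estimated correlation, but fry adjusted p = 0.0249. The promoters of apoptosis Bbc3 (-0.74) and Bcl2l11 (-0.47) were among the falls. Of cytoskeleton and adhesion genes, 2 of 28 tested genes rose and 1 fell (2 and 1 adjusted over the list alone), with camera adjusted p = 0.496, with Itgax (0.99), which shares 10.5% of its sequence words with other genes, among the rises and Sptbn1 (-0.58) the fall. Of cell cycle genes, 1 of 31 tested genes rose and 0 fell (0 and 0 adjusted over the list alone), with camera adjusted p = 0.561, the rise being Mcm2 (0.42). Calls were lost without KO replicate 1 for Slc7a11 (adjusted p = 0.0783) and Bcl2l11 (0.0578), without KO replicate 1 or 3 for Ncf4 (up to 0.0559), and without WT replicate 1, WT replicate 2 or KO replicate 3 for Mcm2 (up to 0.0900). The log2 fold change of Slc7a11 was 0.22 on the log2(FPKM + 1) scale, and that of Hmox1 was 0.52 without both libraries that stand apart. Of replication-dependent histones, 0 of 4 tested genes rose and 0 fell (0 and 0 adjusted over the list alone), with camera adjusted p = 0.736.

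The remaining marker lists held 1 to 8 tested genes each, and none passed camera in edgeR with the 6 libraries and no trend removed. The eosinophil list passed, as lower in KO, with limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1), a length trend removed, or WT replicate 3 left out (adjusted p = 0.0285 to 0.0468). By fry, the dendritic cell, NK cell, eosinophil, endothelial and sex-linked lists each had adjusted p = 0.0288. Called members were the dendritic marker Fscn1 (0.84), the B cell factor Ebf1 (2.47), the NK granule gene Nkg7 (-2.11), the mast cell enzyme Hdc (-0.77), the platelet gene Ppbp (-0.58) and the endothelial receptor Kdr (-0.84). Leaving out 1 library ended the call of Ebf1 in 3 fits (adjusted p of up to 0.115, without WT replicates 1 or 2 or KO replicate 3), Hdc in 4 (0.114, all but WT replicate 3 and KO replicate 3), Ppbp in 5 (0.109, all but WT replicate 3) and Kdr in 4 (0.0698, all but WT replicate 2 and KO replicate 2). Ebf1 had 0.994, 0.322 and 1.87 CPM in the KO libraries, and its log2 fold change ranged from 0.031 to 2.91 over 22 alternatives. Its call and that of Ppbp were lost with limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1), and its call also with limma-voom. On the log2(FPKM + 1) scale the log2 fold changes were -1.12 for Nkg7, -0.48 for Hdc, -0.25 for Kdr and 0.47 for Eif2s3y, and that of Ppbp was -0.36 without WT replicate 2. No tested gene of the eosinophil, erythroid, osteoclast or T cell lists was called in edgeR. The B cell list had a median of -0.48 and a mean of 0.49, with Ebf1 above 0 and the other 2 of 3 tested genes below 0. Camera pointed against both median and mean for the mast cell and osteoclast lists. Of the sex-linked genes, the Y-linked Eif2s3y (0.71) and Ddx3y (0.74) rose, Ddx3y from 9.50 CPM in WT to 16.1 in KO, a call lost without KO replicate 3 (adjusted p = 0.0549). Xist and Tsix of this list were not analysed here, and whether the groups differed in donor sex was not tested.

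The tests of explanations below, other than that of other splits of the samples, were chosen after the result was seen. The real split called 1790 genes and the highest of the other 9 splits 0 in edgeR. Each of these 9 put KO and WT libraries into both of its groups. The difference between KO and WT then adds to the spread within groups and lowers the calls. Their low counts were thus largely set by the design and carry little weight. At an unadjusted p under 0.05, the other splits gave 52 to 1980 genes and the real split 3445. The split with 1980 parted WT replicates 1 and 2 and KO replicate 2 from the other libraries, as the second principal component does. In all, 1 of 10 splits gave as many genes, and 10 splits are too few for a share under 0.05.

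Stromal markers were higher in KO, with Col1a2 at 176 ± 31.2 CPM in KO against 77.3 ± 15.3 in WT (SD, n = 3). A larger share of the same stromal cells, as the sole source of these transcripts, would raise them by a common fold. Instead, 3 of 11 markers departed from the list's mean shift at a limma adjusted p under 0.05, Dcn and Pdgfra upward and Col3a1 downward. A lower share of macrophages would raise markers of other cells alike, but the median was 0.91 for the stromal and -0.29 for the granulocyte precursor list (two-sided permutation over genes, which are not independent replicates, p = 0.00958). Medians of other lists differed in sign (monocyte 0.28, dendritic cell 0.34, platelet -0.26, endothelial cell -0.18). Stromal cells alone in place of macrophages would not raise granulocyte markers. The comparison therefore bears only on a loss of macrophages that raises all other cells. A different kind or state of stromal cells, and expression of part of these genes by the macrophages, with or without Capns1, stay open and were not tested.

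The 19 genes of largest fold difference other than Capns1 may partly reflect reads shared with near-identical genes. Their median share of common sequence was 1.09%, against 0.219% in the other called genes (two-sided permutation p = 0.0595), which leaves this open. Sequence variants linked to the targeted locus that act only on genes of their own chromosome would not account for all of them. Of these genes, 15 lie on chromosomes other than that of Capns1 (exact 95% interval of the share 54.4 to 93.9%). Gene position cannot speak to linked variants that act on genes elsewhere, which were not tested. The other 4 (Svip, Spon1, Gdpd3 and Map4k1) share the chromosome of Capns1, which holds 7.84% of tested genes (one-sided exact binomial p = 0.0566). Map4k1 lies nearest of these, at 28982050 to 29003279, against 30186934 to 30198883 for Capns1. Linked variants were not tested as the source of its fall. Within 1 to 20 Mb of Capns1, 15.6 to 20% of tested genes were called, against 14.6% of all (one-sided Fisher's exact p = 0.0802 to 0.388). Neither a difference in strain background elsewhere in the genome nor a biological effect of the knockout was tested as their source.

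The small rise of oxidative phosphorylation and ribosomal protein genes may partly reflect a gene length bias, with a median log2 fold change of 0.22 (SD 0.26) over the 116 genes together. With the length trend of the other genes removed per library, this median was 0.0861 (SD 0.27), and with the GC trend removed it was 0.236, which argues against GC content. After the length correction the genes together still passed a camera test of edgeR statistics at the preset correlation (p = 0.00825), a test not run on them with an estimated correlation. The 4 lists were not tested alone under that correction. With a length trend fitted on all genes, these included, none of the 4 passed alone (camera adjusted p = 0.0906 to 0.191). Before either correction none passed with an estimated correlation (adjusted p = 0.70 to 0.701). A length bias as the whole source and a change related to Capns1 loss cannot be told apart here, because these genes are short, with a median length of 896 bases against 3514 for all tested genes.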
